A study of Fundulus heteroclitus with 75 samples.

How the data were processed

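Whole embryos of the Atlantic killifish (Fundulus heteroclitus) at developmental stage 35, 10 days after fertilization, were profiled by bulk RNA sequencing. Per the labels, the embryos came from F1 or F2 generation fish reared in the laboratory and were exposed in water to PCB-126 or to its solvent DMSO. The labels give the day of fertilization as the start of exposure in one place and 1 day after fertilization in another. PCB-126 is a coplanar polychlorinated biphenyl that binds the aryl hydrocarbon receptor (AHR). Total RNA was extracted with Trizol and libraries were made with the NEBNext Ultra RNA kit, per the labels' protocols.

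The 75 libraries fall into 17 groups, taken from the labels. There are 8 populations, each at 0 and 200 ng/L, and Elizabeth River also at 2000 ng/L. Per the labels, Bridgeport (BP), Elizabeth River (ER), New Bedford Harbor (NBH) and Newark (NWK) have evolved tolerance, and the other 4 populations are sensitive: Block Island (BI), Flax Pond (FLAX), King's Creek (KC) and Sandy Hook (SH). The tolerant populations hold 37 libraries and the sensitive populations 38. Block Island, Flax Pond, Sandy Hook and Elizabeth River were of the F1 generation (40 libraries) and the others of the F2 (35 libraries), so that generation and tolerance overlap: 3 of the 4 tolerant populations are F2 and 3 of the 4 sensitive populations are F1. The labels say that each tolerant population was paired with a nearby sensitive one without naming the pairs. The pairs used here, NBH with BI, BP with FLAX, NWK with SH and ER with KC, come from knowledge of the study's populations. In Elizabeth River the names inside the count files exchange the 200 and 2000 ng/L libraries relative to the labels; the labels were followed, and exchanged and pooled doses were tried as alternatives. Nothing in the labels says that the samples of a group came from separate families or vessels, so p-values measure the spread between these samples, which may be partly technical.

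Per the submitters' processing notes, Trimmomatic, BWA and featureCounts of the Subread package were used. Per the file headers, the authors counted reads per gene with featureCounts 2.0.0, with a minimum mapping quality of 30, primary alignments only and read pairs counted as fragments; no strand option was set, so overlapping genes on opposite strands are not told apart. The deposited values are whole, unnormalized counts of fragments per gene, with 1 counting command in all files. The genome build is not given in the sources used here; coordinates printed are those of the deposited files (scaffold, start and end of the gene). The files hold 25240 genes by NCBI gene number, of which 21610 (85.6%) matched the RefSeq gene table of assembly MU-UCD_Fhet_4.1 and 13833 had a gene name other than a bare locus number. That table was used for names only. A gene without a name is written as GeneID and its number, and so is GeneID105928076, whose name in that table is a prefix followed by a number. Reads that map equally well to near-identical copies fall under the mapping quality minimum, so that closely related or tandem genes, the AHR genes among them, may be undercounted, beyond what the standard errors show.

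Total counts per library had a median of 13933164. The lowest was 13286, in ER control replicate 1, where 4479 genes were detected. The other libraries had between 8231839 and 29533583 counts and 20476 to 23380 genes detected, and the 10 most abundant genes took 5.62% to 21.0% of the counts. No pair of libraries held identical values (0 pairs). ER control replicate 1 was kept in the fits and was left out of group means, principal components and values per library. A run without it is among the alternatives.

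Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes with too few counts were removed with filterByExpr at its default minimum count of 10, which left 21992 genes. Libraries were scaled with TMM factors and fitted in 1 quasi-likelihood model with a mean per group, so that all 17 groups share the estimate of the spread (58 residual degrees of freedom, common dispersion 0.109). Comparisons were contrasts of the group means tested with glmQLFTest, with Benjamini-Hochberg adjustment over all genes tested and a call at an adjusted p under 0.05. The standard error given beside a log2 fold change is the fold change divided by the square root of its F statistic. Normalized levels are TMM-scaled CPM; log2 CPM values use a prior count of 2. The comparisons were the response to 200 ng/L in each population, the mean response of the 4 sensitive and of the 4 tolerant populations, the difference between these means and within each pair (called the interaction), the baseline difference between unexposed tolerant and sensitive embryos overall and within each pair, and, in Elizabeth River, 2000 ng/L against 0 and against 200 ng/L. The overall contrasts treat the 8 populations as fixed groups.

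The response slope of a population is the slope through 0 of its log2 fold changes on the mean log2 fold changes of 3 other sensitive populations, over the genes called in that mean. For a tolerant population it is averaged over the 4 choices of 3. Slopes of tolerant and sensitive populations were compared with a two-sided exact permutation test. Gene lists were fixed before the data were examined, as were the design, the other settings to be tried and the rule for named genes. Changes to the lists and to that rule are stated below. The 23 lists with enough members were tested with camera in limma 3.58.1 on voom values with the preset correlation, and again with an estimated correlation, with Benjamini-Hochberg adjustment over the lists of a comparison. The lists cover AHR target genes and AHR components; phase 2 enzymes, oxidative stress, heat shock, hypoxia, p53, interferon and complement genes; markers of heart muscle, skeletal muscle, cartilage and bone, photoreceptors, lens, neurons, liver, exocrine pancreas and red blood cells; and genes of the cell cycle, sterol synthesis, oxidative phosphorylation, ribosomes and retinoid and thyroid signalling. Only matches by gene symbol were used, since no gene descriptions were used here, so parts of the lists fixed by description were not applied. Genes without a name are therefore in none of the lists.

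Named genes follow a fixed rule, changed in one respect. As fixed, it asked for a gene description other than uncharacterized. Without descriptions, a gene name other than a bare locus number was asked for in its place. For the sensitive mean, the tolerant mean, the interaction and the baseline, the rule takes the 10 largest log2 fold changes each way among named genes called with a mean log2 CPM of at least 1 and the same direction in all 4 populations or pairs. For single populations and pairs it takes the 3 largest each way, with no overlap between the libraries compared (pair interactions have no overlap rule). All members of the lists of AHR targets and AHR components are reported, and for other lists the 3 members with the smallest p. Genes outside this rule are said to be chosen after their values were seen.

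The tests were run on simulated counts drawn from the real means and library sizes for 21894 genes, with 200 genes changed. In the sensitive mean, edgeR recovered 93% of genes changed by log2 1 and 100% of those changed by log2 2, and 5.85% of its calls were unchanged genes. In Flax Pond alone it recovered 27% and 97%, and in the interaction 65% and 99%. In the tolerant mean and the baseline, which held no change, it called 0 genes, as did limma-voom and DESeq2. The simulated response slopes averaged 0.954 in sensitive and 0.0119 in tolerant populations, and of the 21 lists simulated camera called the 1 made to rise and 0 random ones. Genes were drawn independently, with a preset spread and a mean per gene shared by all populations. The simulation therefore held no correlated genes, population differences or libraries apart, and cannot show how the tests behave with these. In the simulated sensitive mean, unchanged genes made up 10.6% of DESeq2's calls and 4.5% of limma-voom's.

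Same-numbered libraries of a population were checked for pairing by the correlation of their deviations from the group means. In KC all 4 such pairs correlated above 0.1 (0.130 to 0.309), though none correlated best with its own number, and KC values with the replicate number as a block are given where they change a call. In the other populations at least 1 pair did not reach 0.1. Alternatives were DESeq2 1.42.0, limma-voom with and without library weights, other size factors (RLE), no low-count filter, the replicate number as a block, fits of a single population or pair, populations as replicates, averages within generations, exchanged or pooled Elizabeth River doses, and leaving out each library in turn with the dispersions held. Library weights, runs without BI control replicate 3 and BP control replicate 3, and runs without ER control replicate 4 were added after the data were seen. Their effects are given in the closing section. Figures were drawn with matplotlib 3.10.9.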

Results

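Gene expression was measured in 75 libraries of whole killifish embryos from 8 Atlantic coast populations, 4 tolerant and 4 sensitive to PCB-126, a potent agonist of the aryl hydrocarbon receptor. The sensitive populations were Block Island (BI), Flax Pond (FLAX), Sandy Hook (SH) and King's Creek (KC), and the tolerant populations were New Bedford Harbor (NBH), Bridgeport (BP), Newark (NWK) and Elizabeth River (ER). Unexposed and 200 ng/L embryos were represented by 5 and 4 libraries in BI, 5 and 5 in FLAX, 5 and 5 in SH, 5 and 4 in KC, 4 and 4 in NBH, 5 and 5 in BP, 4 and 4 in NWK, and 5 and 3 in ER. ER had 3 more libraries at 2000 ng/L. Library totals had a median of 13933164 counts, and all but ER control replicate 1 (13286 counts) lay between 8231839 and 29533583. Over the 2000 most variable genes, the first and the second principal component carried 14.6% and 8.25% of the variance. Libraries are named below by group and replicate number.

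The first question was which genes respond to PCB-126 in embryos of sensitive populations. CYP1A, the cytochrome P450 that is the classic transcriptional target of the AHR, rose most among the named genes, by log2 5.61 ± 0.72 (SE) in the mean of the 4 sensitive populations. Its median level was 4.38 CPM in the 20 unexposed sensitive libraries, and its mean was 833 ± 474 CPM (SD, n = 18) in the exposed ones. The forkhead transcription factor gene foxq1a rose from 1.72 ± 0.910 (SD, n = 20) to 16.0 ± 10.4 CPM (SD, n = 18). The AHR repressor gene ahrr, whose product opposes AHR signalling, rose from 6.63 ± 2.08 to 24.997 ± 16.0 CPM, and fgf7, a fibroblast growth factor gene, from 0.696 ± 0.723 to 12.8 ± 10.8 CPM. In the deposited coordinates CYP1A lies on scaffold NW_012234324.1 (1272850 to 1276403), foxq1a on NW_012224480.1 (1754588 to 1755816), ahrr on NW_012224938.1 (23269 to 95602) and fgf7 on NW_012234451.1 (545528 to 557606).

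**Figure D1:**
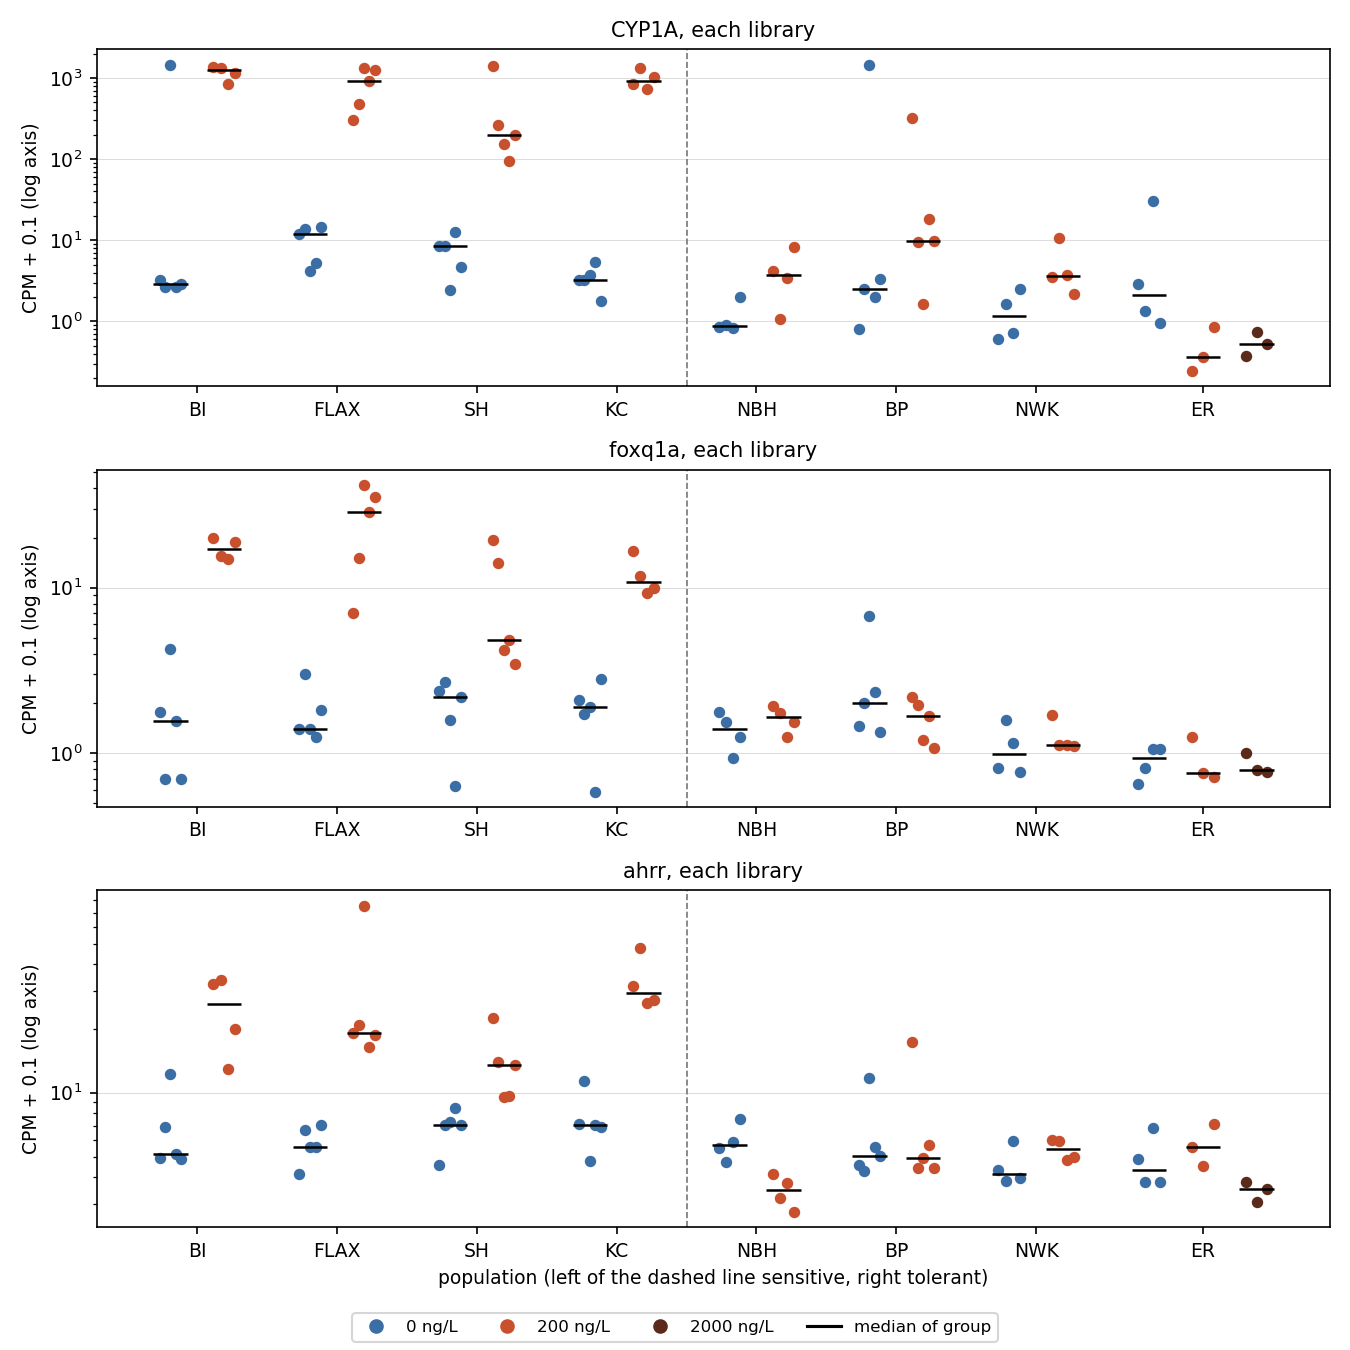
Levels of CYP1A, foxq1a and ahrr in each library (CPM plus 0.1, log axis) by population and PCB-126 concentration; points are libraries, bars are group medians, and ER control replicate 1 is left out. Exposed sensitive libraries held 95.3 to 1407 CPM of CYP1A, and 1 control each of BI and BP held 1465 and 1448 CPM.

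In edgeR's quasi-likelihood test of the sensitive mean, 900 of 21992 genes were called, 577 higher and 323 lower, and 782 of them had the same direction in all 4 populations. Of the calls, 182 rose and 53 fell more than 2-fold. The adjusted p was 5.70e-16 for foxq1a, 3.36e-12 for ahrr, 6.08e-10 for fgf7 and 6.67e-08 for CYP1A. The other named genes with the largest rises were acsl5, a fatty acid activating enzyme (log2 2.69 ± 0.33), slc5a11, a sodium-coupled sugar transporter (2.43 ± 0.27), the amine oxidase gene aoc1 (2.31 ± 0.43), clec3bb (2.22 ± 0.46), b2m, the light chain of MHC class I (1.92 ± 0.53), and apoeb, an apolipoprotein E gene (1.90 ± 0.23). The rise of b2m rested on FLAX exposed replicate 2, without which it was log2 0.20 (adjusted p = 0.844). The CYP1A rise was 7.30 without the BI and BP controls with high CYP1A.

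The largest falls among named genes were those of saa, serum amyloid A (log2 -2.66 ± 0.71), si:dkey-205h13.2 (-1.72 ± 0.36), the parvalbumin gene pvalb3 (-1.44 ± 0.41), the inducible heat shock gene hspa1b (-1.44 ± 0.36), the elastin gene elnb (-1.41 ± 0.22) and ace, angiotensin converting enzyme (-1.38 ± 0.30). They were followed by unc119.2 (-1.15 ± 0.28), mybpha, a myosin binding protein gene (-1.14 ± 0.22), rag1, the recombinase of developing lymphocytes (-1.04 ± 0.31), and fgl1b (-1.03 ± 0.29). Of the 20 genes with the largest changes, 15 kept the call when each of the 38 libraries was left out in turn. Besides b2m, saa was lost without SH control replicate 4 (adjusted p = 0.0696). Calls were kept in 31 of the 38 fits by pvalb3 and rag1 and in 34 by fgl1b, with the highest adjusted p without KC control replicate 2 (0.145), BI control replicate 5 (0.0901) and SH control replicate 3 (0.0661).

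**Figure D2:**
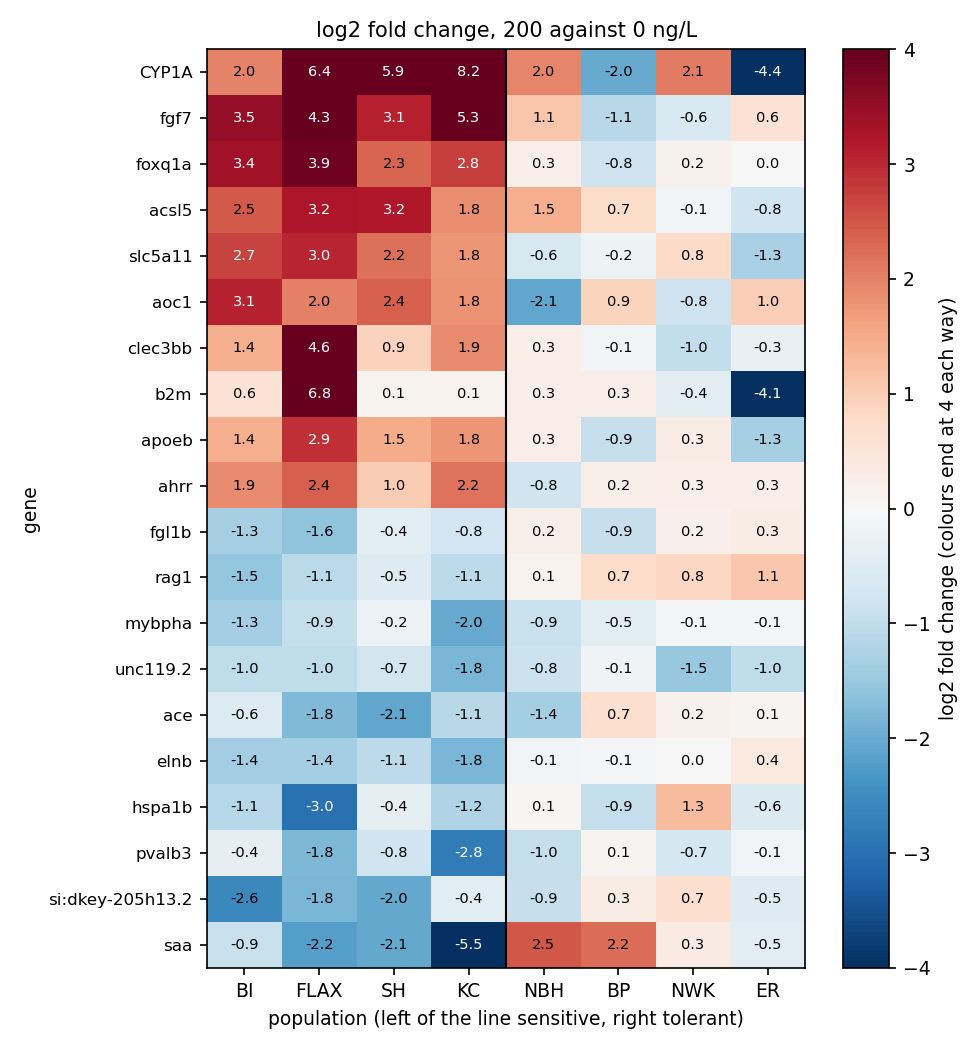
Log2 fold change at 200 against 0 ng/L in each population for the 20 named genes with the largest changes in the sensitive mean, with 4 sensitive populations to the left of the line and 4 tolerant to the right. Colours end at 4 each way and cells print the value; foxq1a reached 3.36, 3.90, 2.32 and 2.77 in BI, FLAX, SH and KC and lay between -0.81 and 0.27 in the tolerant populations.

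Of the 8 measured genes in the list of AHR targets, 5 rose: CYP1A, foxq1a, ahrr, nqo1, a quinone reductase (log2 1.77 ± 0.30), and foxf2a, a forkhead gene next to foxq1a (1.45 ± 0.31; NW_012224480.1, 1756964 to 1759843). The same number, 5, was called when adjusted over the list alone, and the list rose in camera's test (adjusted p = 5.61e-19; adjusted p = 8.90e-08 with an estimated correlation). The other members, wfikkn1 (0.04), gfi1b (0.18) and cbr1 (0.12), were not called. The list was matched by gene symbol, so AHR targets among the genes without a name are not in it. Among 10 AHR components, 3 rose: the AHR gene ahr2 (GeneID 105917025; 0.93 ± 0.22), a second AHR gene, AHR2 (GeneID 105937229; 0.67 ± 0.16), and arnt, the dimerization partner (0.28 ± 0.07). The cochaperone gene ptges3l fell by 0.58 (adjusted p = 0.0270, and 0.0577 without BI exposed replicate 3). Adjusted over the list alone, 3 components rose and 2 fell, and the list as a whole was not called (adjusted p = 0.690). AHR1 (0.08), arnt2 (0.02), hsp90ab1 (0.17), hsp90aa1.2 (-0.41), ptges3a (-0.26) and ptges3b (-0.17) were not called.

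Lists of oxidative stress and metabolism were tested next. Of 19 NRF2 and oxidative stress genes, 3 rose, keap1a (log2 0.72), gclc (0.23) and nfe2l2a (0.39), and 6 when adjusted over the list alone (list adjusted p = 0.0268; adjusted p = 0.465 with an estimated correlation). In the list of 7 phase 2 and transport genes, abcc2 (0.59) and gstt1b (0.36) rose, 2 also when adjusted over the list alone (list adjusted p = 0.185). Of 20 sterol synthesis genes 0 were called, over all genes or adjusted over the list alone, in edgeR's test, with hmgcra at 0.67 ± 0.25 (list higher, adjusted p = 0.0268; adjusted p = 0.465 with an estimated correlation). Of 13 p53 and apoptosis genes likewise 0 were called, with fas at 0.68 ± 0.23 (list higher, adjusted p = 0.0153; adjusted p = 0.155 with an estimated correlation). Among 28 retinoid and thyroid genes, bco1, a carotene cleaving enzyme (1.02), and tpo, thyroid peroxidase (1.49), rose, 3 when adjusted over the list alone (list adjusted p = 0.839); tpo was at 20.7 CPM in FLAX exposed replicate 2 and at most 0.730 CPM in the other FLAX libraries. In the list of 27 hypoxia and glycolysis genes, ddit4 rose (0.56), 1 also when adjusted over the list alone (list adjusted p = 0.990).

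Lists of skeletal muscle, cartilage and bone, eye and cell cycle genes were lower in the mean of the sensitive populations by the preset correlation. The eye and cell cycle lists did not move one way in the 4 populations. Of 30 cartilage and bone genes 5 fell, with bglapl, an osteocalcin-type gene, at log2 -1.73, spp1, osteopontin, at -0.96 and epyc at -0.63, and 7 when adjusted over the list alone (list adjusted p = 2.17e-05; adjusted p = 0.465 with an estimated correlation). Of 29 skeletal muscle genes 3 fell, mybpc2b (-0.58), ldb3b (-0.52) and casq1a (-0.54), and 4 when adjusted over the list alone (list adjusted p = 8.68e-08; adjusted p = 0.465 with an estimated correlation). Of 33 photoreceptor genes 3 fell, the cone opsin gene opn1lw1 (-0.76), cnga3a (-0.57) and grk7a (-0.61), and 9 when adjusted over the list alone, with 32 of the 33 at values below 0 (list adjusted p = 8.68e-08; adjusted p = 0.465 with an estimated correlation). In 13 lens genes and 34 cell cycle genes, edgeR called 0 members over all genes and 0 adjusted over the list alone, and the lists were lower with adjusted p = 0.00131 and 0.0220. Their calls were lost with adjusted p = 0.465 and adjusted p = 0.736 with an estimated correlation. In BI 28 of the 33 photoreceptor genes had values above 0 (median log2 0.32, list not called, adjusted p = 0.0717), and the medians in FLAX, SH and KC were -0.52, -0.35 and -1.11. Values above 0 were also found for 9 of the 13 lens genes in BI and 10 in FLAX, while the lens medians in SH and KC were -0.45 and -1.23. Of the 34 cell cycle genes 30 in BI and 25 in FLAX had values below 0, but 25 in SH (median 0.11, list adjusted p = 0.230) and 20 in KC (median 0.05, 0.243) had values above 0. Skeletal muscle genes had values below 0 for 20, 24, 24 and 27 of the 29 members in BI, FLAX, SH and KC.

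Of 24 liver and plasma protein genes, apoeb rose, and 1 also when adjusted over the list alone (list higher, adjusted p = 0.0498; adjusted p = 0.754 with an estimated correlation), while in BI 13 of the 24 had values below 0. Of 6 exocrine pancreas genes, cpb1, carboxypeptidase B (log2 1.66), rose, and 2 when adjusted over the list alone (list higher, adjusted p = 0.0268; adjusted p = 0.465 with an estimated correlation); in SH 3 of the 6 had values below 0. In the interferon list of 15 genes, trim25l (0.90), irf1b (1.16) and b2m rose, 4 when adjusted over the list alone, and the list was not called (adjusted p = 0.0612). FLAX exposed replicate 2 held 889 CPM of b2m and 45.9 CPM of the immunoproteasome gene psmb8a, against at most 2.17 and 1.02 CPM in the other 9 FLAX libraries. Complement and acute phase genes (saa lower, c6 higher at 0.65; adjusted p = 0.746) and 9 red blood cell genes (rhag higher at 0.90; 0.540) were not called as lists. Neither were 24 heart muscle genes (adjusted p = 0.153; hand2 at -0.61), 36 neuronal genes (0.0983; slc17a7a at -0.35) or 15 heat shock genes (0.557; hspa8b at 0.72). The lists of 8 ribosomal protein genes (0.990; rpl5a at -0.14) and 3 oxidative phosphorylation genes (0.449; sdha at 0.20) were not called either. The heat shock list did not hold hspa1b, which fell in the sensitive mean, or hspb9, which fell in FLAX.

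The response of each sensitive population was then tested by itself, and foxq1a rose in all 4. In BI it rose by log2 3.36 ± 0.47, with slc5a11 (2.70 ± 0.55), ahrr (1.88 ± 0.35) and the myosin gene myo15b (2.31 ± 0.50), and golgb1 fell by 1.00. In FLAX CYP1A rose by 6.43 ± 1.48, fgf7 by 4.26 ± 0.86, foxq1a by 3.90 ± 0.46 and ahrr by 2.40 ± 0.35, while hspa1b (-2.998 ± 0.74), hdhd5 (-1.87 ± 0.33) and the small heat shock gene hspb9 (-1.83 ± 0.37) fell. In SH foxq1a rose by 2.32 ± 0.45 and nln fell by 1.31. In KC CYP1A rose by 8.16 ± 1.62, fgf7 by 5.31 ± 0.93, foxq1a by 2.77 ± 0.46 and ahrr by 2.18 ± 0.35, and bglapl fell by 4.11. CYP1A was at 5.88 in SH (adjusted p = 0.132) and 1.99 in BI (0.733), neither called. BI control replicate 3 held 1465 CPM of CYP1A, against 2.53 to 3.15 CPM in the other BI controls and 854 to 1352 CPM in exposed BI libraries. Without it and BP control replicate 3 the BI fold change was 8.75 (adjusted p = 2.92e-07).

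The edgeR calls numbered 45 in BI (39 higher, 6 lower), 717 in FLAX (541 and 176), 14 in SH (11 and 3) and 18 in KC (15 and 3). The lower calls besides nln and bglapl, named after their values were seen, were GeneID105919983 (log2 -2.33) and GeneID105927708 (-1.25) in SH, and fam102ba (-2.73) and GeneID105929299 (-1.76) in KC. The AHR target list rose in BI, FLAX, SH and KC with adjusted p = 5.99e-11, 7.92e-09, 3.42e-09 and 2.14e-14, and stayed called with an estimated correlation. In KC the lens list was lower (adjusted p = 1.10e-18; adjusted p = 0.0158 with an estimated correlation), as was the photoreceptor list, with 27 of 33 members lower when adjusted over the list alone (adjusted p = 9.82e-25; adjusted p = 0.0930 with an estimated correlation, and 0.00443 with the replicate number as a block). The skeletal muscle list of KC was lower (adjusted p = 1.01e-11; adjusted p = 0.130 with an estimated correlation, and 0.0195 with the block) and the red blood cell list higher (6.45e-04; adjusted p = 0.130 with an estimated correlation, and 0.0497 with the block). By the preset correlation it added calls of the cartilage and bone (lower, adjusted p = 0.0126), pancreas (higher, 0.00872) and liver lists (higher, 0.0342), which had adjusted p = 0.576, 0.122 and 0.688 with an estimated correlation. In SH the liver list was higher (adjusted p = 4.54e-07; adjusted p = 0.563 with an estimated correlation), and in FLAX the p53 list (adjusted p = 0.00601; adjusted p = 0.0881 with an estimated correlation). By the preset correlation SH also had skeletal muscle (adjusted p = 2.02e-04) and photoreceptor genes (0.00631) lower and NRF2 genes (0.0223) higher, with adjusted p = 0.784, 0.877 and 0.563 with an estimated correlation. In FLAX cartilage and bone (adjusted p = 8.88e-04), photoreceptor (0.00158), heart muscle (0.00273), cell cycle (0.00341), skeletal muscle (0.00372) and neuronal genes (0.0146) were lower and sterol synthesis genes (0.00981) higher, with adjusted p = 0.310 with an estimated correlation for heart muscle and 0.612 for the others. In BI cell cycle (adjusted p = 6.98e-08) and cartilage and bone genes (4.14e-04) were lower, with adjusted p = 0.818 and 0.923 with an estimated correlation.

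Several of these counts and calls depended on single libraries. The BI count fell to 23 without BI control replicate 1 or exposed replicate 2, and was 26 to 28 without exposed replicate 5 or control replicates 2 or 5; myo15b kept its call in 4 of 9 fits, with an adjusted p of up to 0.0760 (without control replicate 5). FLAX had 416 and 462 calls without control replicates 3 and 1, of which 394 and 408 were among the 717, and without the latter hspa1b was at log2 -1.72 and not called (adjusted p = 0.202). SH had 2, 6 and 7 calls without control replicates 4, 1 and 2, and 3 without exposed replicate 1, where foxq1a had an adjusted p of 0.168. Most single omissions ended the calls of nln in SH, kept in 3 of 10 fits (adjusted p up to 0.220, without control replicate 4), and bglapl in KC, kept in 2 of 9 (up to 0.411, without exposed replicate 2). The SH call of foxq1a was kept in 8 of 10 fits, and the KC call of CYP1A was lost without control replicate 5 (0.0517). FLAX exposed replicate 2 held 334 genes more than 4-fold above every other FLAX library, among them cd74a at 1241 CPM (others at most 3.51), the thyroglobulin gene tg at 57.8 (3.75), the myoglobin gene mb at 145 (10.2) and pvalb7 at 283 (22.5). Of the 541 higher FLAX calls 124 were among these genes, and without the library FLAX had 564 calls, 388 higher and 176 lower.

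Genes shared between sensitive populations were more numerous than independent lists would give. FLAX and BI shared 21 higher calls against 0.959 by chance, FLAX and KC 14 against 0.369, FLAX and SH 9 against 0.271, and BI and KC 9 against 0.0266. No library is used by more than 1 population. Higher in 2 or more populations were 27 genes, including, named after their values were seen, sp8a, etv4, anpepa, sult1st6, muc13b and p2rx1, and 2 were lower. In all 4 populations 4 genes were higher: foxq1a, and GeneID105916579, GeneID105926177 and GeneID105919170, which were named after their values were seen. GeneID105916579 rose by log2 4.45, 3.86, 5.99 and 5.86 in BI, FLAX, SH and KC, and its values in NBH, BP, NWK and ER were -0.36, 0.10, 0.58 and -0.23.

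The second question was whether tolerant embryos respond to the same concentration. In the mean of the 4 tolerant populations, CYP1A was at log2 -0.60 ± 0.84, foxq1a at -0.09 ± 0.26 and ahrr at -0.00 ± 0.19, none of them called. Tolerant libraries held a median of 1.52 CPM of CYP1A without PCB-126 (n = 17) and 3.56 CPM with it (n = 16, 0.145 to 323). Levels of foxq1a were 1.51 ± 1.40 and 1.30 ± 0.434 CPM (SD), and those of ahrr 5.31 ± 1.94 and 5.49 ± 3.31 CPM. The AHR target list was not called in this mean (adjusted p = 0.947). BP control replicate 3 held 1448 CPM of CYP1A, against 0.711 to 3.27 CPM in the other BP controls and 1.53 to 323 CPM in exposed BP libraries; its foxq1a (6.65 CPM) and ahrr (11.6 CPM) were also above those of the other BP controls (at most 2.24 and 5.43). Without it and BI control replicate 3, CYP1A was at 1.18 in the tolerant mean (adjusted p = 1.00), and in BP at 5.12 (adjusted p = 0.0154) in place of -2.01. BP exposed replicate 1 held 323 CPM of CYP1A and the other 4 exposed BP libraries 1.53 to 18.3 CPM. Its slope on the response of the sensitive populations was 0.347, against -0.0253 to 0.0453 in these 4. At marker genes of the populations its correlation with BP was -0.249, and it was nearest to ER. The correlation with BP minus that with ER was -0.929, the lowest such margin among 71 libraries. The fold change of 5.12 in BP includes this library, and no fit left out both it and BP control replicate 3.

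In the tolerant mean edgeR called 0 genes (822 at an unadjusted p under 0.05), limma-voom 0 and DESeq2 3, and edgeR called 1 without BP control replicate 1. By population edgeR called 0 genes in NBH (1114 at an unadjusted p under 0.05; DESeq2 9, limma-voom 0), 1 in BP, 1 in NWK and 53 in ER. The single calls, named after their values were seen, were GeneID105918109 in BP (log2 0.88) and GeneID105929619 in NWK (6.41). Leaving out 1 library gave 0 to 3 calls in NBH, 0 to 4 in BP and 0 to 4 in NWK. CYP1A was at 1.95 in NBH, 2.08 in NWK and -4.43 in ER (-2.02 without ER control replicate 4, adjusted p = 1.00), not called. Lists that moved in the tolerant mean by the preset correlation were lower for photoreceptor (adjusted p = 7.76e-10), neuronal (1.39e-06) and lens genes (5.17e-04). They were higher for cell cycle (8.20e-09), cartilage and bone (2.55e-05), heat shock (0.00203) and red blood cell genes (0.0203). These calls were lost, with adjusted p = 0.478 with an estimated correlation for photoreceptor, neuronal, cell cycle, heat shock and red blood cell genes and adjusted p = 0.497 with an estimated correlation for lens and cartilage and bone genes. Among 13 lens genes and 33 photoreceptor genes, 0 members were called by edgeR here, adjusted over the list alone included. By population 5, 6, 4 and 5 lists were called in NBH, BP, NWK and ER by the preset correlation, and 0 with an estimated correlation (adjusted p = 0.878, 0.912, 0.947 and 0.878 with an estimated correlation).

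In ER, 50 of the 53 calls were lower and 3 higher: the ribosomal S6 kinase gene rps6kb1a (log2 1.38), GeneID105928076 (1.64) and GeneID105939562 (2.29), the first and last named after their values were seen. The named fall by the rule was gstz1 (-1.34 ± 0.31). With the 200 and 2000 ng/L labels exchanged, as the names inside the count files have them, 60 genes were called, 0 higher and 60 lower, 41 of them among the 53. ER control replicate 4 stood apart: 313 genes were more than 4-fold above every other ER library, including the hemopexin gene hpxa at 5719 CPM (others at most 3.57), the trypsinogen gene prss1 at 917 (1.32), the egg envelope gene FhChgL at 675 (0.797) and fabp10a, a liver fatty acid binding protein, at 1726 (94.7). Of the 50 lower calls 48 were among these genes. Without this library edgeR called 0 genes in ER; GeneID105928076 was then at 1.53 and gstz1 at -0.99, and in 8 fits that left out 1 library each they kept their calls in 2 and 4. Leaving out ER control replicates 2 or 3 gave 88 and 85 calls, and exposed replicates 1, 2 and 3 gave 1, 7 and 0. The liver list was lower in ER (1 fallen, 9 adjusted over the list alone; adjusted p = 3.88e-04; adjusted p = 0.878 with an estimated correlation).

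ER embryos were also tested at 2000 ng/L, 10 times the common concentration. CYP1A was at log2 -4.19 ± 1.98 against 0 ng/L, not called, and the 60 genes called by edgeR were all lower (limma-voom called 0 and DESeq2 71), 58 of them among the 313 genes high in ER control replicate 4. Without that library edgeR called 0 genes, and CYP1A was at log2 -1.77 (adjusted p = 1.00), foxq1a at 0.00 and ahrr at -0.27. Leaving out ER control replicates 2 or 3 gave 110 and 115 calls, and 2000 ng/L replicates 4, 5 and 6 gave 15, 9 and 9. Between 2000 and 200 ng/L edgeR called 0 genes (320 at an unadjusted p under 0.05), limma-voom 1 and DESeq2 5.

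The third question was whether the responses differ between tolerant and sensitive populations, tested as the difference between the mean responses. CYP1A differed by log2 -6.22 ± 1.07 (adjusted p = 2.81e-04), fgf7 by -4.05 ± 0.68, foxq1a by -3.18 ± 0.35 (7.80e-09), slc5a11 by -2.76 ± 0.40, acsl5 by -2.36 ± 0.49, apoeb by -2.32 ± 0.34, ahrr by -1.87 ± 0.26 (2.58e-06) and the follistatin-like gene fstl3 by -1.80 ± 0.32, all lower in tolerant embryos. Without BP control replicate 3 CYP1A was at -4.43 (adjusted p = 0.00308), fgf7 at -3.34 (9.24e-04) and foxq1a at -3.01 (2.70e-09). Without BI control replicate 3 as well, CYP1A was at -6.13. Differences of b2m (-2.92) and aoc1 (-2.57) were also called; b2m was at -1.21 without FLAX exposed replicate 2 (adjusted p = 0.283) and at -1.66 without ER control replicate 4 (0.262), and aoc1 had an adjusted p of 0.127 without NBH control replicate 3. In the opposite direction were saa (3.81 ± 1.04), rag1 (1.73 ± 0.44), elnb (1.46 ± 0.31), smtnl1 (1.22 ± 0.33), mocs1, a molybdenum cofactor gene (1.19 ± 0.29), entpd5a (1.15 ± 0.29), the constitutive heat shock gene hsc70 (1.12 ± 0.30), hdhd5 (1.08 ± 0.24), c18h19orf54 (1.05 ± 0.28) and GeneID105928076 (0.98 ± 0.25).

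In edgeR 284 genes differed in response, 90 higher and 194 lower in tolerant embryos, and 262 had the same direction in all 4 pairs; 186 were called without ER exposed replicate 2. Averaged within the F1 and F2 generations, the contrast had 83 calls, 13 higher and 70 lower, 76 of them among the 284. Of the 20 named genes 14 kept the call without any 1 of 72 libraries. The others kept it in 29 to 60 of the 72 fits, with the highest adjusted p for saa without NBH exposed replicate 3 (0.223), smtnl1 and hsc70 without ER exposed replicate 2 (0.0801 and 0.129) and c18h19orf54 without ER exposed replicate 1 (0.0648). Of 8 AHR targets 4 differed (CYP1A, foxq1a, ahrr and nqo1 at log2 -1.73), and 5 when adjusted over the list alone (list adjusted p = 1.10e-10; adjusted p = 6.26e-05 with an estimated correlation); nqo1 was lost without BP control replicate 3 (adjusted p = 0.0543). Lists whose response was higher in tolerant embryos were cartilage and bone (adjusted p = 2.06e-08; adjusted p = 0.623 with an estimated correlation), cell cycle (1.10e-06) and skeletal muscle (2.97e-06; for both, adjusted p = 0.655 with an estimated correlation). In these lists edgeR called 0 members; 3 cartilage and bone genes passed when adjusted over the list alone.

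Response slopes summarize the same contrast over the genes called in other sensitive populations. They were 0.706 in BI, 0.965 in FLAX, 0.515 in SH and 0.430 in KC, and 0.0630 in NBH, -0.0957 in BP, 0.0265 in NWK and -0.134 in ER. The means were 0.654 ± 0.237 (SD, n = 4) and -0.0349 ± 0.0945 (SD, n = 4). The difference of -0.689 had an exact permutation p of 0.0286, the smallest that 70 splits of the 8 populations allow. These splits take no account of the pairs or of generation, so the test by itself does not separate tolerance from generation. The slopes of the populations that cross them went with tolerance. ER, the only tolerant F1 population, was at -0.134, against 0.515 to 0.965 in the sensitive F1 populations. KC, the only sensitive F2 population, was at 0.430, against -0.0957 to 0.0630 in the tolerant F2 ones. This argues against generation as the whole account of the slopes, though only ER and KC cross them. Without BI control replicate 3 and BP control replicate 3 the BP slope was 0.151, with BP exposed replicate 1 kept. Without ER control replicate 4 the ER slope was -0.0401. Treating populations as replicates gene by gene, limma called 0 genes (2315 at an unadjusted p under 0.05).

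**Figure D3:**
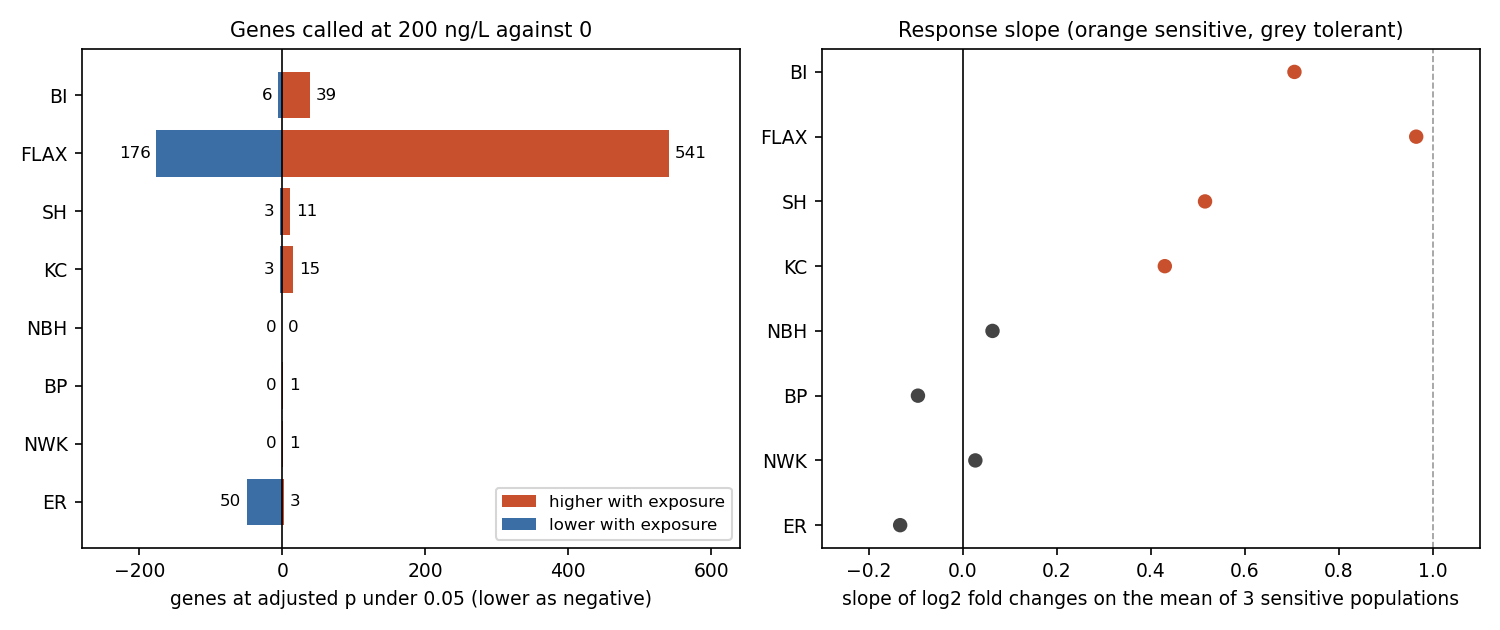
Left, number of genes called at 200 against 0 ng/L in each population (higher to the right, lower to the left). Right, response slope of each population with all libraries kept, with 4 sensitive populations between 0.430 and 0.965 and 4 tolerant ones between -0.134 and 0.0630.

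Within pairs, the response of BP differed from that of FLAX in 101 genes, 18 higher and 83 lower. The response was lower in BP for CYP1A (log2 -8.44 ± 1.88), foxq1a (-4.71 ± 0.64), ahrr (-2.16 ± 0.48), b2m (-6.54) and the MHC class II chaperone gene cd74a (-6.13), and higher for hdhd5 (2.01), rgs19 (1.69) and the kinase gene alpk3a (1.68). Without BP control replicate 3 there were 12 calls, CYP1A was at -1.30 (adjusted p = 0.873) and foxq1a at -4.05 (1.86e-04), and ahrr (0.105), hdhd5 (0.0765) and alpk3a (0.0811) were lost. Without FLAX exposed replicate 2 there were 51 calls, with b2m at 0.31 and cd74a at 1.91. In 20 fits without 1 library each, rgs19 and cd74a kept the call in 5 and b2m in 15, with the highest adjusted p of rgs19 without BP exposed replicate 4 (0.220). The count was between 46 and 66 without BP control replicate 4, BP exposed replicates 2, 3 or 4, or FLAX control replicates 2 or 3, and 159 and 228 without BP control replicate 5 and FLAX exposed replicate 1.

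ER and KC differed in response in 13 genes, all lower in ER, with CYP1A at log2 -12.59 ± 2.70, si:ch73-86n18.1 at -11.65 and prss1 at -10.05. None was called without ER control replicate 4, where si:ch73-86n18.1 was at 1216 CPM and at most 0.992 CPM in other ER libraries. Without it CYP1A was at -10.18, si:ch73-86n18.1 at -1.65 and prss1 at 0.53 (adjusted p = 1.00 for each), and leaving out 1 library gave 0 to 40 calls, with CYP1A, si:ch73-86n18.1 and prss1 called in 6, 6 and 4 of 17 fits. In NBH against BI edgeR called 0 genes (1474 at an unadjusted p under 0.05; DESeq2 17, limma-voom 0), but 5 without BI control replicate 3 and 1 without BI exposed replicate 4. Without BI control replicate 3 and BP control replicate 3 there were 11, with CYP1A at -6.78 (adjusted p = 0.0202), foxq1a at -3.73 (0.00105) and ahrr at -2.97 (0.00105). In NWK against SH edgeR called 0 genes (1272 at an unadjusted p under 0.05; DESeq2 2, limma-voom 0), and 1 without NWK control replicate 3, SH control replicates 3 or 5, or SH exposed replicate 3.

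The last question was whether unexposed tolerant and sensitive embryos differ. The glutathione transferase gene gstt1b was higher in tolerant controls by log2 0.66 ± 0.11 (adjusted p = 0.00134), at 47.5 ± 10.6 (SD, n = 17) against 30.4 ± 6.97 CPM (SD, n = 20); it lies on NW_012224582.1 (110643 to 115691). The collagen gene col9a1a was higher by 0.87 ± 0.20 and cthrc1b by 0.84 ± 0.18, and so were fgfbp2b (0.77) and vtna, vitronectin (0.65). Higher too were si:ch1073-126c3.2 (2.78 ± 0.67), the tyrosine aminotransferase gene tat (1.56), the coagulation factor gene f9b (1.49), pmt (1.39) and the glutathione peroxidase gene gpx4a (0.71). The glucocorticoid responsive cochaperone gene fkbp5 was lower (-3.70 ± 0.79), as were tmem269 (-1.04), phkg2 (-0.999), the circadian nuclear receptor gene nr1d2a (-0.99), lmo7b (-0.79), abcg1 (-0.66) and the photoreceptor genes gucy2d (-0.70) and cnga3a (-0.70). No member of the lists of AHR targets and AHR components was called. CYP1A was at -1.12 ± 0.70 and ahrr at -0.34 ± 0.18. Both values include BI control replicate 3 and BP control replicate 3. These held 1465 and 1448 CPM of CYP1A, against at most 3.15 and 3.27 CPM in the other controls of BI and BP. Their ahrr was also higher, at 12.1 and 11.6 CPM against at most 6.77 and 5.43. The baseline of CYP1A and ahrr without these libraries is not given here, so their lack of a call decides little.

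In edgeR 64 genes differed at baseline, 40 higher and 24 lower, and 46 had the same direction in all 4 pairs. Averaged within the F1 and F2 generations there were 265 calls, 241 higher and 24 lower, 44 of them among the 64. As in the interaction, this average gives ER, the only tolerant F1 population, the weight of the 3 tolerant F2 populations together, and KC likewise among the sensitive ones. It was not run without ER control replicate 4, without which the ER and KC baseline fell from 289 to 17 calls. Of 18 named genes, gstt1b and cthrc1b kept the call without any 1 of 38 libraries. In the 38 fits, calls were kept in 9 by f9b, 13 by tat, 14 by cnga3a, 15 by gpx4a, 17 by si:ch1073-126c3.2 and nr1d2a, 21 by abcg1, 23 by col9a1a and 28 to 37 by the other 8. Without ER control replicate 4 si:ch1073-126c3.2 was at log2 1.23 (adjusted p = 0.326), tat at 0.71 (0.322), f9b at 0.82 (0.247), pmt at 0.74 (0.149) and gpx4a at 0.42 (0.149). Without KC control replicate 2 fkbp5 was at -2.91 (0.0793), tmem269, phkg2, gucy2d, abcg1 and fgfbp2b had an adjusted p of 0.0780, nr1d2a of 0.126 and lmo7b of 0.0566. The highest adjusted p of col9a1a (0.0848), vtna (0.0559) and cnga3a (0.0919) were those without BP control replicate 3, NWK control replicate 2 and SH control replicate 4. The count lay between 11 and 140, moving by more than 1.5 times without 21 of the 38 libraries. The lowest counts were 11, 12, 13 and 14 without KC control replicate 2, NBH control replicate 1, NWK control replicate 2 and BP control replicate 3, and the highest 97, 100 and 140 without ER control replicate 3, NWK control replicate 1 and SH control replicate 3. With populations as replicates limma called 0 genes (1175 at an unadjusted p under 0.05).

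By list, liver and plasma protein genes were higher in tolerant controls, with 3 of 24 called (vtna, apoc1 at log2 1.37 and the fibrinogen gene fgg at 1.12) and 17 when adjusted over the list alone (list adjusted p = 3.77e-09; adjusted p = 0.444 with an estimated correlation). In ER control replicate 4 this list had a median log2 difference of 2.75 from the mean of the other ER controls, replicate 1 left out. Each of 36 other controls, taken against its own group in the same way, reached at most 0.81. Photoreceptor genes were lower, with 1 of 33 called and 9 when adjusted over the list alone (list adjusted p = 6.93e-17; adjusted p = 0.444 with an estimated correlation). Cartilage and bone genes (adjusted p = 9.54e-07), cell cycle genes (1.97e-06), complement genes (0.00326) and NRF2 genes (0.0419) were higher and neuronal genes (6.15e-07) lower, each with adjusted p = 0.444 with an estimated correlation. Skeletal muscle genes were lower (adjusted p = 3.94e-04; adjusted p = 0.460 with an estimated correlation).

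Within pairs, ER and KC controls differed in 289 genes, 276 higher and 13 lower in ER. The complement gene c8b was higher (log2 2.17 ± 0.46), as was gstt1b (0.83 ± 0.22), and the phosphatase gene dusp29 was lower (-1.78 ± 0.44). Of the 276 higher calls 181 were among the genes high in ER control replicate 4, and 17 genes were called without it, c8b (adjusted p = 0.353), gstt1b (0.293) and dusp29 (0.145) not among them; in 10 fits without 1 library each these kept the call in 9, 4 and 6. NWK and SH differed in 22 genes, with kpna2 (1.11) and pnpo (0.83) higher and ankrd27 (-1.30), ica1 (-1.16) and grin2ca (-1.0002) lower in NWK; these 5 kept the call in 2, 2, 6, 2 and 3 of 9 fits and were lost without SH control replicate 4, where 1 call was left, and 121 were called without SH control replicate 3. NBH and BI differed in 4 genes, including the myosin light chain gene myl9b (1.17 ± 0.22; called in 4 of 9 fits, with an adjusted p of up to 0.115, without NBH control replicate 4), with 0 to 7 calls when 1 library was left out. BP and FLAX differed in 0 genes by edgeR (1108 at an unadjusted p under 0.05; DESeq2 23, limma-voom 0), and in 14, 8, 1 and 1 without FLAX control replicates 1, 3, 2 and 4.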

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

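The tests on BI control replicate 3, BP control replicate 3, ER control replicate 4 and FLAX exposed replicate 2 were chosen only after the results were seen, as were the splits of the samples for the 8 single responses at 200 ng/L and for both means. Those of the Flax Pond spread and depth and the other splits were chosen before.

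The total count and the levels of CYP1A, foxq1a, ahrr, nqo1 and foxf2a were checked in groups of 4 or 5 libraries, in 90 checks. In 10 of these, all for a gene, a library lay far from the others of its group by Dixon's ratio, where chance gives about 1 in 20 groups. No total count was flagged, that of ER control replicate 1 included. CYP1A was at log2 CPM 10.52 in BI control replicate 3 (others 1.42 to 1.72), 10.50 in BP control replicate 3 (others -0.24 to 1.77) and 1.03 in NBH control replicate 4 (others -0.20 to -0.07). The AHR repressor gene ahrr was at 3.55 in BP control replicate 3, 4.11 in BP exposed replicate 1 and 6.24 in FLAX exposed replicate 3, where the others reached at most 2.48, 2.51 and 4.39. The forkhead gene foxf2a was at -2.27 in BP control replicate 5 and -1.74 in FLAX control replicate 1, nqo1 at 1.84 in KC control replicate 2, and foxq1a at 0.79 in NWK exposed replicate 1.

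The high CYP1A of BI control replicate 3 and BP control replicate 3 went with part of the exposure response, with slopes of 0.463 and 0.602 on the response of the sensitive populations. An exposed sample of the same population under a control label stays open. The BI library lay below the 4 exposed BI libraries (slopes of 0.654 to 0.868). The BP library lay above the 5 exposed BP libraries (-0.0253 to 0.347). So few libraries set no firm limit, and exposed libraries spread more widely in SH (0.212 to 0.878). RNA of exposed embryos mixed into a control would leave other response genes at a like share; in BI this was argued against, with CYP1A at 125% of the exposed level and 15 other response genes at most at 74.4%, and in BP it stays open, with CYP1A at 174% and another gene at 182%. A library of another population remains open, since the correlation with the own population at 500 marker genes was 0.434 in BI (SH 0.466) and 0.0849 in BP (NBH 0.445), and 54 of 71 other libraries were nearest their own population. No biological explanation was tested.

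ER control replicate 4 stood above the other ER libraries in genes of liver and pancreas. RNA of these tissues added to an otherwise like library is a candidate explanation. Relative to the mean of the other controls of the group, medians of the liver and pancreas lists were at log2 2.75 and 7.27. In 36 other controls they reached at most 0.81 and 2.46. Of 6 lists of other tissues 0 lay outside the range of these controls. These ranges span all populations and are wide, so whether the library was otherwise like is not decided. Photoreceptor genes were at 1.416 and cartilage and bone genes at -1.201, both near an end of their range. Skeletal muscle, lens, heart muscle and neuronal genes were at 0.641, 0.617, -0.209 and 0.197. FhChgL (675 CPM, others at most 0.797) and esr1 (21.6, 1.16), which the liver of egg-producing females expresses, were high too, as were b2m (141, 2.74) and cd74a (366, 18.3), but added RNA would not by itself bring rag1 to 0.349 CPM, against 4.39 to 16.8 CPM in 9 other ER libraries, so it stays open as the whole account. The 45 genes more than 4-fold below every other ER library decide nothing, since up to 176 such genes were found for other controls. A library of another population also stays open (correlation with ER 0.354, with KC 0.213), and no biological explanation was tested.

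Flax Pond held 717 calls, against 45, 14 and 18 in the other sensitive populations. A smaller spread between its libraries was not found, with a median SD of 0.369, within the 0.260 to 0.483 of KC, BI and SH. All groups share the estimate of the spread in the fit, so the SD of a population's own libraries says little about its count. In fits of each population alone FLAX had 103 calls, KC 69, BI 5 and SH 2, so the gap to KC depended on the shared fit. Greater depth was argued against by 698 calls after its libraries were thinned to 76.8% of their reads. Transcripts of another tissue in FLAX exposed replicate 2 were argued against as the whole cause by 564 calls without that library. The excess stays unexplained: the response slope was higher in FLAX than in BI (0.965 and 0.706), but not without BI control replicate 3 and BP control replicate 3 (0.802 and 0.873), where BI had 75 calls, and the origin of the population was not tested.

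The responses of tolerant and sensitive populations differed, by the test of the interaction, in 284 genes, of which the 20 given here are those with the largest differences under the fixed rule, 10 each way; 14 of the 20 kept the call without any 1 library. The tolerant minus sensitive difference was log2 3.81 for saa, 1.73 for rag1, 1.46 for elnb, 1.22 for smtnl1, 1.19 for mocs1, 1.15 for entpd5a, 1.12 for hsc70, 1.08 for hdhd5, 1.05 for c18h19orf54 and 0.98 for GeneID105928076. It was -6.22 for CYP1A, -4.05 for fgf7, -3.18 for foxq1a, -2.92 for b2m, -2.76 for slc5a11, -2.57 for aoc1, -2.36 for acsl5, -2.32 for apoeb, -1.87 for ahrr and -1.80 for fstl3.

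Under 5% of the splits of the same samples gave as many calls, a share not corrected for the number of comparisons, in the sensitive mean (900; 1 of 100 splits as large, highest other 66), BI (45; 1 of 100, 10), FLAX (717; 1 of 100, 264), KC (18; 3 of 100, 110) and the overall interaction (284; 1 of 35, 11). The same held for the BP and FLAX interaction (101; 2 of 100, 167) and the baselines of NBH and BI (4; 1 of 100, 3), NWK and SH (22; 3 of 100, 124) and ER and KC (289; 1 of 100, 276). Of these, the BP and FLAX interaction had 12 calls without BP control replicate 3, the NWK and SH baseline 1 without SH control replicate 4, the ER and KC baseline 17 without ER control replicate 4 (the splits had a median of 94) and the NBH and BI baseline 0 without BI control replicate 1, so chance is less firmly excluded for these 4. In KC the 14 splits that part 4 same-numbered pairs, as the real one does, gave at most 1 call besides it, and the splits as large parted 0 or 1 pair (110 and 18 calls). Chance was not excluded for SH (14; 10 of 100, 3142), BP (1; 49 of 100, 7), NWK (1; 20 of 35, 6), ER (53; 29 of 56, 272), ER at 2000 ng/L (60; 32 of 56, 392), the ER and KC interaction (13; 14 of 100, 214) or the baseline overall (64; 16 of 35, 445). Where the real count was 0 every split is as large by construction, so nothing follows about chance for NBH (35 of 35, highest other 13), the tolerant mean (100 of 100, 30), the interactions of NBH and BI (100 of 100, 159) and NWK and SH (100 of 100, 3079) or the baseline of BP and FLAX (100 of 100, 2). For 2000 against 200 ng/L the 10 splits were too few (0 calls, highest other 2). Splits that called several times the real count, as in SH, KC, ER, NWK and SH, ER and KC and the overall baseline, point to a structure of the samples other than the groups compared.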

How the results depend on the processing

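Of 202 alternative counts of calls, 110 lay within 1.5 times the count reported and 92 beyond; limma-voom with library weights and the runs without BI control replicate 3 and BP control replicate 3 or without ER control replicate 4 were chosen after seeing the data. The overall counts for the sensitive mean (900) and the slope difference (-0.689) kept within 1.5 times or their direction in the alternatives run, except that library weights gave 1532 calls; the slope difference was -0.716 to -0.627 in 4 other settings. For named genes, 100 of 108 calls were kept with RLE size factors and 100 with no low-count filter, 101 of 102 with DESeq2, 63 of 108 with limma-voom and 82 with library weights. The 108 are the 94 calls taken by size of change and the called members of both AHR lists. Unless said otherwise, the cause was not tested. Depth limits ER control replicate 1 (13286 counts) most; without it ER had 53 calls and 59 at 2000 ng/L.

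DESeq2 called 107 genes in BI, 25 in SH, 9 in NBH, 5 in BP, 6 in NWK, 5 for 2000 against 200 ng/L, 3 in the tolerant mean and 117 at baseline. Its pair interactions were NBH_BI 17, BP_FLAX 173, NWK_SH 2 and ER_KC 21, and its baselines NBH_BI 37, BP_FLAX 23 and NWK_SH 75. limma-voom called 0 in SH, 3 in BP, 0 in NWK, 2 in ER, 0 at 2000 ng/L, 1 for 2000 against 200 ng/L, 9 at baseline, 2, 0 and 41 in the baselines NBH_BI, NWK_SH and ER_KC, 35 and 1 in the interactions BP_FLAX and ER_KC, and 49 of the 94 calls taken by size of change; cd74a in the BP_FLAX interaction turned to log2 0.048. With library weights it called 137 in BI, 4 in SH, 632 in KC, 1 in NBH, 23 in BP, 0 in NWK, 7 in ER, 1 at 2000 ng/L, 303 for 2000 against 200 ng/L, 2 in the tolerant mean, 705 in the interaction, 562 at baseline, 23 and 58 in the interactions NBH_BI and ER_KC and 271, 514 and 482 in the baselines NBH_BI, BP_FLAX and ER_KC; cd74a was at 0.44.

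Replicate numbers did not pair the samples over all populations: 14 of 34 same-numbered pairs correlated above 0.1 and 7 correlated best with their own number. In KC all 4 pairs did the former and 0 the latter; with the block KC had 18 calls (13 of them among the 18 without it), and its 5 named genes kept their calls. With the replicate number as a block, calls were 17 in BI, 262 in FLAX, 0 in SH, BP, NWK and ER, 17 at 2000 ng/L, 11 for 2000 against 200 ng/L, 51 in the interaction, 42 at baseline, 25 and 1 in the interactions BP_FLAX and ER_KC, 5 in the baseline NWK_SH and 53 of the 94; with the block cd74a was at 0.45 in BP_FLAX and prss1 at 1.35 in ER_KC.

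Fits of that population or pair alone, which hold fewer samples, called 5 in BI, 103 in FLAX, 2 in SH, 69 in KC, 0 in BP, NWK, ER and ER at 2000 ng/L, 15, 1 and 8 in the interactions BP_FLAX, NWK_SH and ER_KC and 0 in the baselines NBH_BI and NWK_SH. Populations as replicates gave 0 and 0 for the interaction and baseline, and averages within generations 83 and 265. Pooled ER doses gave 144 in ER and 55 in the ER_KC interaction, exchanged doses 30 in the latter, RLE 1 in NBH, and leaving out ER control replicate 1 gave 34 in the baseline NWK_SH. At an adjusted p under 0.01, 15 genes rather than 29 were shared. At the usual adjusted p under 0.05, 7 of 72 list calls held with an estimated correlation.

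Without BI control replicate 3 and BP control replicate 3, calls were 75 in BI, 5 in BP, 23 at baseline, 11 and 11 in the interactions NBH_BI and BP_FLAX and 8 and 1 in the baselines NBH_BI and BP_FLAX. Without ER control replicate 4 they were 0 in ER, 0 at 2000 ng/L, 41 at baseline, 0 in the ER_KC interaction and 16 in the ER_KC baseline, and prss1 was at 0.53 in that interaction.

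Leaving out each library in turn gave 23 to 67 calls in BI, 416 to 942 in FLAX, 2 to 19 in SH, 13 to 17 in KC, 0 to 3 in NBH, 0 to 4 in BP, 0 to 4 in NWK, 0 to 88 in ER, 0 to 115 at 2000 ng/L, 0 to 0 for 2000 against 200 ng/L, 727 to 1044 in the sensitive mean and 0 to 1 in the tolerant mean. The interaction had 186 to 386 and the baseline 11 to 140. Pair interactions had 0 to 5 (NBH_BI), 12 to 228 (BP_FLAX), 0 to 1 (NWK_SH) and 0 to 40 (ER_KC), and pair baselines 0 to 7, 0 to 14, 1 to 121 and 17 to 371.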

Other observations

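Both tests below were chosen before their results were seen; the genes named here were chosen after their values were seen. In the mean of the sensitive populations further genes with roles in the intestine and in absorption were called higher: the meprin genes mep1a.2 (log2 1.87) and mep1a.1 (1.65), the mucin gene muc13b (1.60), the nuclear receptor gene hnf4g (1.55), anpepa, an aminopeptidase (1.27), and dpp4, a dipeptidyl peptidase (0.82). Transcription factor genes sp8a (1.65) and etv4 (1.06), the growth factor receptor gene erbb3a (1.11), the sulfotransferase gene sult1st6 (1.202) and the cytochrome P450 gene CYP2P3 (1.95) were called higher as well. No list of intestinal genes was fixed beforehand, so no theme was tested.

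Genes that rose with exposure lay side by side more often than random sets. Of 19473 neighbouring pairs, 40 had both members among the 577 risen genes, against a median of 13 and a highest value of 28 in 10000 random sets (permutation p = 1e-04, the smallest they can give). Fallen genes formed 9 such pairs (random median 4, highest 13). Among the pairs are foxq1a and foxf2a, mep1a.2 and mep1a.1, and GeneID105916580, GeneID105916579 and GeneID105916581, at log2 4.87, 5.04 and 2.19. Shared regulation of neighbours may contribute. So may reads assigned to the wrong one of related copies, though reads that map equally well to both fall under the mapping quality minimum. These were not told apart.

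A hypothesis that tolerant controls resemble exposed sensitive embryos at the response genes was not borne out. With separate control libraries for the response and the baseline, the mean slope of the baseline difference on the response was -0.0374 (-0.0472 over 287 genes and -0.0276 over 85). With shared controls the slopes were 0.102 and 0.00460, and the covariances were 0.170 and 0.135 against -0.0317 and -0.102 with separate ones.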
